A study of Homo sapiens with 139 samples.

How the data were processed

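Optic nerve head tissue from 3 animals was measured by digital spatial profiling (GeoMx), in which barcodes are released from chosen regions of a tissue section and sequenced to count probes bound to RNA. The labels give each animal a control eye and an eye with experimental glaucoma, which was induced by laser, and they describe 5-micron sections of fixed tissue in paraffin. The series title names non-human primates, while the organism field of all 139 libraries names human. The 103 ocular libraries are therefore treated as animal tissue, and the other 36 libraries as the human cell lines and tissues that their labels name. How the regions of interest were chosen on the sections, and what the numbers in the region labels stand for, is not given in the sources used here.

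The deposited files hold counts per probe for each library, as whole numbers without normalization. Per the file headers they were written by the GeoMx NGS Pipeline, version 2.0.0, and record raw, trimmed, stitched and aligned reads before a list of probe identifiers with their counts. Read duplicates had been collapsed before deposit, per the file headers, since the counts are far below the aligned reads, with 93.4 to 98.6% of aligned reads removed as duplicates. A probe missing from a file was taken as a count of 0. The files list 18815 probe identifiers and do not pair them with gene names, and 0 of them matched the gene table used here, so results are given by probe identifier and the gene lists and cell type markers fixed beforehand could not be run. Negative-control probes could not be told from the others without that table, so the background level of the assay is unknown and no probe was called detected or undetected.

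Library size, the total count per library, ran from 7763 to 1266518 (median 397340) in the ocular libraries and from 60957 to 12151840 in the reference materials. A library filter asked for at least 1000 raw reads, 75% aligned reads and 50% duplicate saturation, and all 139 libraries passed. No 2 libraries held identical counts. All 1337 pairs of ocular libraries from one group were compared over the probes with at least 20 counts in the pair (627 or more, median 18282). By a chi-square test 0 agreed within counting noise, with a lowest ratio of chi-square to degrees of freedom of 1.05, and each library was kept. With so many probes the test also rejects repeats with slight extra noise, so it cannot exclude technical repeats. Animal 2 gave 52 libraries against 25 and 26, and whether some are repeats is not given in the sources used here.

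The animal was the replicate (n = 3). Counts were summed per animal, eye and region into 18 sums of 200388 to 6681408 counts. These were fitted in R 4.3.3 with edgeR 4.0.16 (TMM normalization, filterByExpr, glmQLFit and glmQLFTest, two-sided, Benjamini-Hochberg adjustment over all probes, threshold 0.05). The model held an animal-by-region block with 9 levels and a glaucoma term for each region, and differences between those terms tested whether the effect differed between regions. Regions were compared in the 9 sums of the control eyes with the animal as a block. Numbered labels within a region were compared in control eyes with the animal as a block, and the 17 reference materials run in both batches were compared between batches with the material as a block. Standard errors (SE) are of the log2 fold change and were derived from the fold change and its F statistic. Levels are given as CPM, counts scaled to a common library total with TMM factors, and log2 CPM used a prior count of 2.

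The eyes of an animal come from one animal and one batch, per the labels, which is where the pairing comes from. The control and the glaucoma sum of an animal deviated from their group means in the same direction in all 9 animal and region pairs. Correlations were 0.169 to 0.770 across probes, which are not independent replicates. Animal 2 is the only animal of batch 2, and a batch shift alone could make all 9 correlations positive. They are therefore not a check of which eyes belong together.

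Probe sets for the reference materials took up to 100 probes at least 1 log2 unit above every other material in both batches (pseudocount 1), and sets of at least 15 probes were tested with camera in limma 3.58.1 at a preset correlation of 0.01. Only 5 sets were large enough. Before the data were examined, the groups, tests, alternatives and the rule for named probes were written down. That rule takes, per comparison, up to 2 probes with the largest rise and up to 2 with the largest fall among probes past the threshold with the same direction in all 3 animals, or the 2 smallest p-values in each direction where none pass. Alternatives were DESeq2 1.42.0, upper-quartile factors, other filters, the mean of log2 CPM per animal with limma-trend, voom with a random eye block, the region alone in the fit, no block, and each animal left out.

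The tests were checked on simulated counts of 18815 probes with the depths and spreads of the real sums. Of these probes 67, 67 and 66 were changed 1.5-fold, 2-fold and 4-fold. The counts were drawn independently around 1 common profile, with no animal or batch differences and no single libraries far from the rest. Recovered shares and false calls hold for that setting, and real data with such libraries can give more false calls. For the glaucoma comparison in the lamina, 65.7% of 2-fold changes and 13.4% of 1.5-fold changes were recovered. For that in the prelamina these shares were 85.1% and 29.9%, and for that in the retrolamina 100% and 68.7%. In every simulated comparison of eyes or regions all 4-fold changes were recovered by edgeR. Its false calls numbered 2, 6 and 14 for glaucoma in the lamina, prelamina and retrolamina, and 5, 13 and 17 for lamina against prelamina, lamina against retrolamina and prelamina against retrolamina. They exceeded a share of 0.05 of all calls in the comparisons that involve the retrolamina, and not in the others. For the lamina labels L2 against L1, edgeR recovered 13.4% of 2-fold changes with 4 false calls, as many as it called in the real data. On the simulated glaucoma comparison in the lamina limma-trend made 44 false calls. It was run there on log2 CPM of the sums, so this count does not describe the alternative with the mean of log2 CPM.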

Results

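Transcript abundance was profiled in 3 regions of the optic nerve head, the place where the axons of the retina leave the eye. The prelamina lies in front of the lamina cribrosa, a sieve of connective tissue, and the retrolamina lies behind it. The 103 ocular libraries held 8 of the prelamina, 8 of the lamina and 36 of the retrolamina from control eyes, and 8, 8 and 35 from eyes with experimental glaucoma. Animals 1, 2 and 3 gave 25, 52 and 26 libraries. Animals 1 and 3 were labelled batch 1 and animal 2 batch 2. Total counts per sum ranged from 200388 to 874816 in the control lamina and from 3384176 to 6681408 in the control retrolamina, so counting error is smallest in the retrolamina. Most probes lay near a common level, with a median of 46.2 CPM and 90% of them between the 5th percentile of 31.7 and the 95th of 74.6, and 465 of the 18815 probes reached at least 2 times the median. The lower of the levels compared below often lies in that range. Since the background is unknown, fold changes are ratios of levels not corrected for it.

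The first question was which transcripts distinguish the regions in control eyes. The retrolamina differed most from the others. Probe RTS0027108 stood at 4208 ± 266 CPM in the control retrolamina (SD, n = 3 animals), 241 ± 14.1 CPM in the lamina and 73.3 ± 3.71 CPM in the prelamina. Its level was 57.2-fold higher in the retrolamina than in the prelamina, and 17.5-fold higher than in the lamina. Probe RTS0038701 followed with 455 ± 45.1 CPM in the retrolamina against 51.0 ± 6.95 CPM in the lamina and 43.1 ± 7.03 CPM in the prelamina. Both differences held in 3 of 3 animals. The rule for named probes requires this of each probe it names past the threshold between regions or eyes, so it is no separate support.

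**Figure D1:**
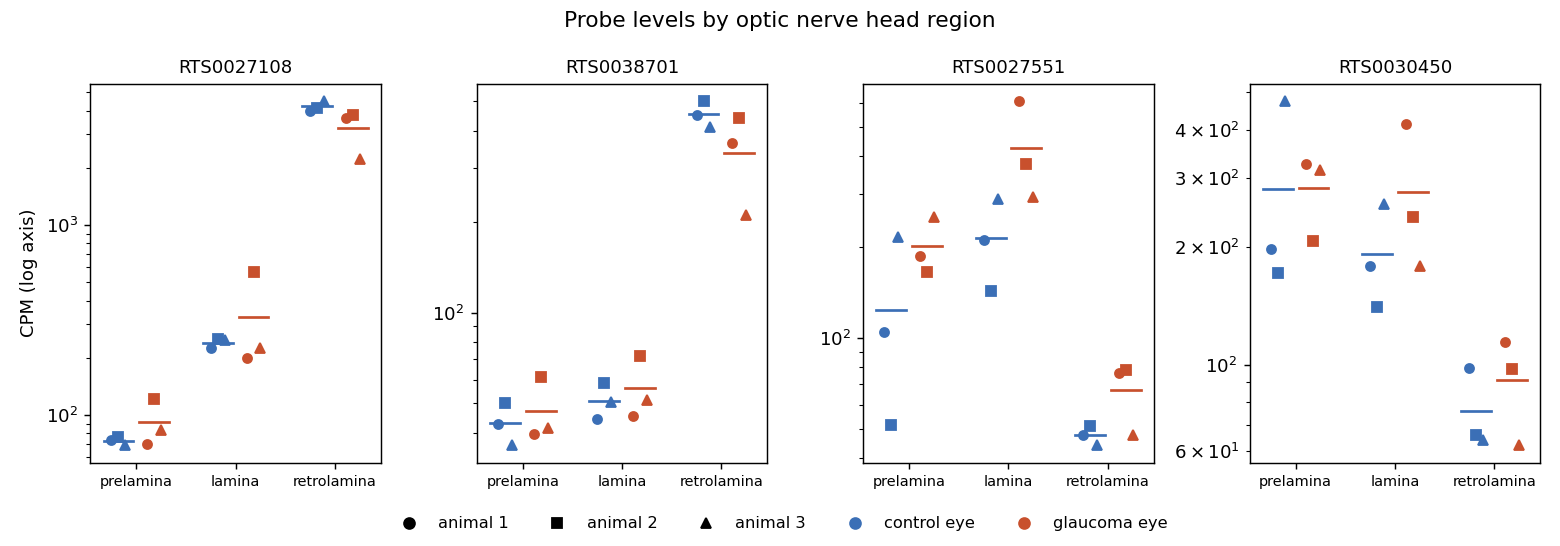
Level of 4 named probes in CPM on a log axis for prelamina, lamina and retrolamina, with 1 point per animal and eye and a bar at the mean of 3 animals. RTS0027108 and RTS0038701 are highest in the retrolamina, at 4208 and 455 CPM in control eyes, while RTS0027551 and RTS0030450 are lowest there, at 47.6 and 76.0 CPM.

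Between prelamina and retrolamina, 244 of 18815 probes passed the threshold in edgeR's quasi-likelihood test, 72 higher in the prelamina and 172 lower. For 50 of the 72, 1 prelamina library held over 50% of the excess, where 26.2% of 4146 probes with little sign of a difference (unadjusted p of at least 0.5, value above 0) gave as much. For the 172 this was so in a median of 0.581% (0 to 11.05%) over 40 draws of 8 retrolamina libraries, a number matched to the prelamina. The 172 had been called on all 36 retrolamina libraries, so the choice of probes was not matched. RTS0027108 was lower in the prelamina by a log2 fold change of -5.84 (SE 0.21, adjusted p = 2.0e-19) and RTS0038701 by -3.40 (SE 0.17, adjusted p = 2.1e-15). In the other direction RTS0030450 was 3.30-fold higher in the prelamina (281 ± 167 against 76.0 ± 19.1 CPM, adjusted p = 1.2e-06). RTS0035997 was 2.70-fold higher there (121 ± 117 against 34.8 ± 8.57 CPM, adjusted p = 0.0036). That value rested on 1 prelamina library of animal 3 at 482 CPM. Without 5 libraries outlying in named probes, left out after their values were seen, its log2 fold change was 0.60 with an adjusted p of 0.16 in edgeR (1.1e-19 to 0.84 over its alternatives). The count with DESeq2 was 118, of which 6 were higher in the prelamina and 112 lower, and the mean of log2 CPM gave 57, of which 1 was higher and 56 lower. With 3 libraries of under 110000 counts left out the count was 235, and with the outlying libraries left out it was 138.

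Between lamina and retrolamina, 143 probes passed, 48 higher in the lamina and 95 lower. For 27 of the 48, 1 lamina library held over 50% of the excess (56.2%), not far above the 40.5% of 4619 probes with as little sign of a difference. For the 95, which had been called on all 36 retrolamina libraries, this was so in at most 5.26% over 40 draws of 8 of them. RTS0027551 was 4.13-fold higher in the lamina (214 ± 72.2 against 47.6 ± 3.58 CPM, adjusted p = 5.4e-07) and was higher in 3 of 3 animals. RTS0051294 was 3.33-fold higher (226 ± 298 against 39.7 ± 6.13 CPM, adjusted p = 0.0028), with an SD above its mean. RTS0027108 was lower by a log2 fold change of -4.13 (SE 0.19, adjusted p = 4.9e-16) and RTS0038701 by -3.19 (SE 0.18, adjusted p = 8.7e-14). DESeq2 called 79 probes, 10 higher and 69 lower. The RTS0051294 difference came mainly from 1 lamina library of animal 3 at 1034 CPM, and its log2 fold change was 0.71 (adjusted p = 0.22 in edgeR, 1.5e-20 to 1.00 over its alternatives) without the outlying libraries, a fit with 83 calls.

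Lamina and prelamina of control eyes differed in 1 probe, RTS0027108, which was 3.27-fold higher in the lamina (241 against 73.3 CPM, SE 0.20 in log2, adjusted p = 2.5e-05) and higher in 3 of 3 animals. It was 1 of 1220 probes with an unadjusted p under 0.05. DESeq2 called 19 probes, all higher in the lamina. Leaving out animals 1, 2 and 3 in turn gave 48, 53 and 6 probes.

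Glaucoma was then set against control eyes in each region, which is the comparison the study's labels are built on. In the retrolamina, 5 probes passed, 4 higher and 1 lower in glaucoma. RTS0027873 was 2.25-fold higher (118 ± 85.3 against 45.9 ± 6.74 CPM, SE 0.19 in log2, adjusted p = 0.015). RTS0026554 was 2.07-fold higher (69.9 ± 39.7 against 31.7 ± 6.36 CPM, SE 0.14, adjusted p = 5.0e-04). RTS0026919 fell by 0.75 on the log2 scale (53.7 ± 4.18 against 90.9 ± 10.7 CPM, adjusted p = 0.039). These 3 probes moved the same way in 3 of 3 animals, which the rule for named probes requires, and so did all 5 that passed. The rises were largest in animal 1. RTS0026919 did not pass without animal 3 either (adjusted p = 0.18 in edgeR), with a log2 fold change of -0.65, and over its alternatives this ran from -0.92 to -0.57. Over 11 alternatives that alter the fit RTS0027873 no longer passed in 5 (adjusted p from 0.0063 to 1.00 in edgeR and the other tools), RTS0026554 in 4 (3.1e-04 to 1.00) and RTS0026919 in 6 (0.014 to 1.00). Voom with a random eye block gave 0 retrolamina probes (159 at an unadjusted p under 0.05) and the mean of log2 CPM with limma-trend 0 (110 at that level). Without animal 1, 0 probes passed in edgeR, with 427 at an unadjusted p under 0.05. DESeq2 with all animals called 4 probes, 3 of them among the 5.

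**Figure D2:**
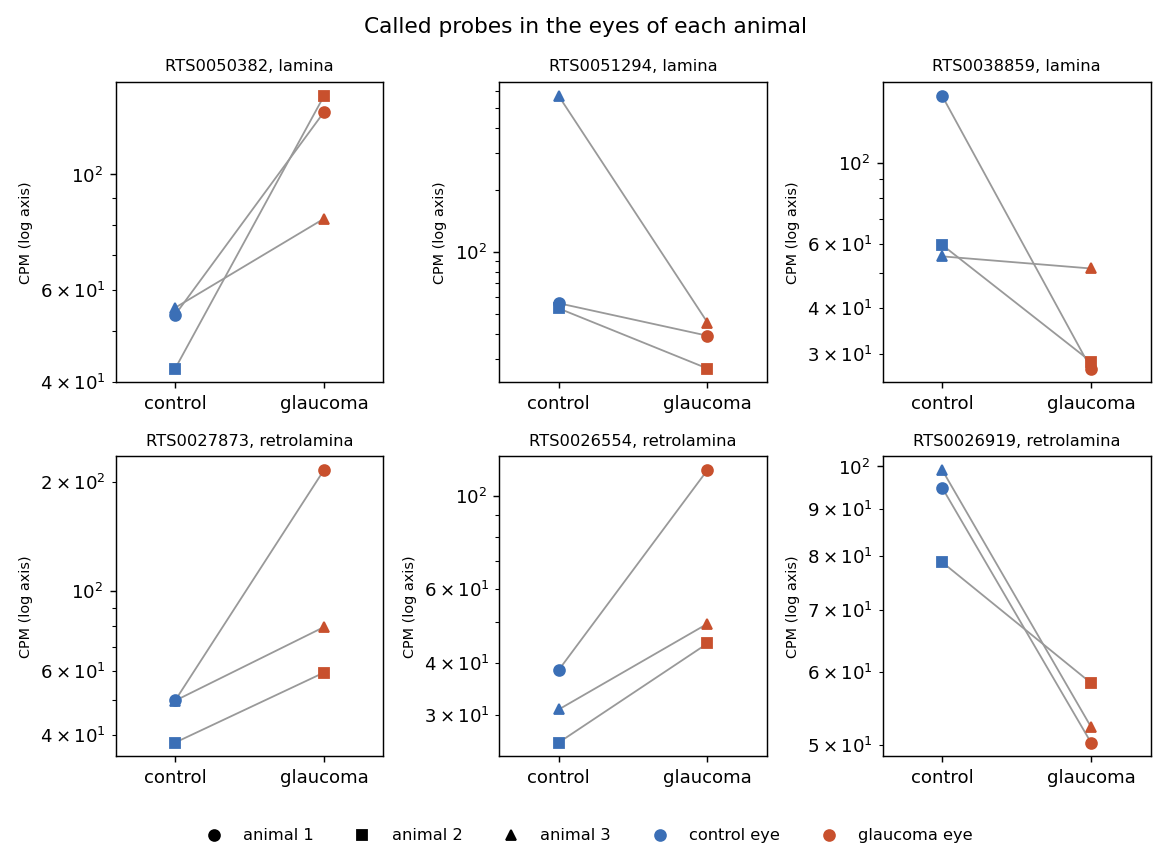
CPM on a log axis of the named probes past the threshold in the lamina (top row) and retrolamina (bottom row), with the control and glaucoma sum of each animal joined by a line. RTS0050382, RTS0027873 and RTS0026554 are higher and RTS0051294, RTS0038859 and RTS0026919 lower in the glaucoma eye of each of the 3 animals, which the rule for named probes requires. The fall of RTS0051294 is mostly that of animal 3. That of RTS0038859 is slight in animal 3, at 55.5 CPM in the control and 51.4 CPM in the glaucoma eye.

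In the lamina, 3 probes passed, 1 higher and 2 lower in glaucoma. Leaving out animals 1, 2 and 3 in turn gave 7, 13 and 11 probes, with 1, 2 and 2 of the 3 among them. RTS0050382 was 2.57-fold higher, at 119 ± 31.8 CPM in glaucoma and 50.5 ± 7.12 CPM in control eyes (SE 0.21 in log2, adjusted p = 0.011), and it was higher in 3 of 3 animals. All 8 glaucoma libraries lay above the control mean of their animal. RTS0051294 fell by 1.96 (37.1 ± 9.25 against 226 ± 298 CPM, adjusted p = 0.021) and RTS0038859 fell by 1.57 on the log2 scale (35.8 ± 13.5 against 89.0 ± 54.6 CPM, adjusted p = 0.021). Each of these falls rested largely on 1 control library, of animal 3 and animal 1. Without the outlying libraries the adjusted p was 0.40 for RTS0051294 and 0.90 for RTS0038859 (log2 fold changes of -0.91 and -0.69), and 0.0094 for RTS0050382, and those libraries had been chosen for their values of RTS0051294, RTS0038859 and other named probes. RTS0050382 did not pass without animal 1 (adjusted p = 0.11) or animal 2 (adjusted p = 0.13), with log2 fold changes of 1.41 and 1.12 against 1.36 with all animals. Over their alternatives the adjusted p in edgeR and the other tools ran from 0.0011 to 1.00 for RTS0050382, 0.00031 to 1.00 for RTS0051294 and 0.0021 to 1.00 for RTS0038859. Upper-quartile factors gave 7 probes.

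In the prelamina, 0 probes passed in edgeR, with 836 at an unadjusted p under 0.05, and DESeq2 also called 0, with 497 at that level. Leaving out animals 1, 2 and 3 in turn gave 3, 11 and 5 probes, and leaving out the outlying libraries gave 2. The smallest p-values, none of which passed, belonged to RTS0020917 (67.6 ± 30.4 in glaucoma against 36.5 ± 3.55 CPM, adjusted p = 0.30) and RTS0036735 (58.8 ± 9.43 against 35.4 ± 2.39 CPM, adjusted p = 0.38) among probes with a higher value. Among those with a lower value they belonged to RTS0028800 (36.7 ± 7.05 against 110 ± 114 CPM, adjusted p = 0.070) and RTS0035701 (47.1 ± 7.92 against 142 ± 126 CPM, adjusted p = 0.12). These 2 control means rested largely on the same library of animal 1, at 419 and 488 CPM. With all libraries of animal 1 in the fit, RTS0028800 passed in edgeR without animal 2 (adjusted p = 0.0015) and without animal 3 (adjusted p = 0.017), and RTS0035701 passed without animal 2 (adjusted p = 7.1e-04). Without animal 1, or without the outlying libraries, the adjusted p was 1.00 for both.

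The glaucoma effect was not shown to differ between regions. The differences of lamina and prelamina, lamina and retrolamina, and prelamina and retrolamina each gave 0 probes in edgeR, with 740, 700 and 491 at an unadjusted p under 0.05. DESeq2 gave 0 in each as well, with 428, 389 and 214 at that level. Without animal 2, 9 and 3 probes passed in the comparisons of lamina and of prelamina with retrolamina, and without animal 1, 4 passed in the first of these.

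None of the 5 reference-material probe sets differed in any of these comparisons. They belonged to BT474, HCC1954, MCF7 (with and without abemaciclib) and MDA-MB-468 (present only as treated with EGF, by its label), which are breast cancer lines, and THP1, a monocytic leukaemia line, and held 50, 25, 21, 25 and 15 probes. The lowest adjusted p was 0.067, for BT474 in the difference of the glaucoma effect between lamina and retrolamina, and it was 0.35 with an estimated correlation.

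Numbered labels within a region were compared in control eyes. Between the prelamina labels PL2 and PL1, 0 probes passed in edgeR (930 at an unadjusted p under 0.05) and 0 in DESeq2 (36 at that level), but leaving out animals 1, 2 and 3 in turn gave 45, 58 and 7. Between the lamina labels, 4 probes were higher in L2 than in L1. RTS0036561 had a mean of 353 CPM in L2 and 40.3 CPM in L1 (log2 fold change 2.74, adjusted p = 0.034) but was higher in 2 of 3 animals, and RTS0022312 had 312 and 59.4 CPM (log2 fold change 2.00, adjusted p = 0.039) and was higher in 3 of 3. These were named after their values were seen. Both means came mainly from 1 of 4 L2 libraries, of animal 1, at 965 and 801 CPM against 57.9 and 112.5 in the next, and in all 4 probes that library held 81.5 to 96.1% of the excess over L1. DESeq2 called 0 of them, with 23 at an unadjusted p under 0.05. Across RL1 to RL5, 13 probes passed in edgeR's F test and 2 with DESeq2, and leaving out animals 1, 2 and 3 in turn gave 43, 54 and 37, with 11, 4 and 8 of the 13 among them.

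The batches differed widely. In the 17 reference materials run in both, 12869 of 18815 probes passed, 6567 higher in batch 2 and 6302 lower, and 992 of them differed at least 2-fold. DESeq2 called 12662. Upper-quartile factors called 12901 but divided them into 5424 higher and 7477 lower, so the direction of small shifts depends on the scaling. Of the 17 batch 1 libraries, 15 were most similar to the batch 2 library of the same material. The first principal component of the 18 ocular sums, with 37.4% of the variance, separated animal 2 from animals 1 and 3. Eyes were compared within an animal, and so within a batch.

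**Figure D3:**
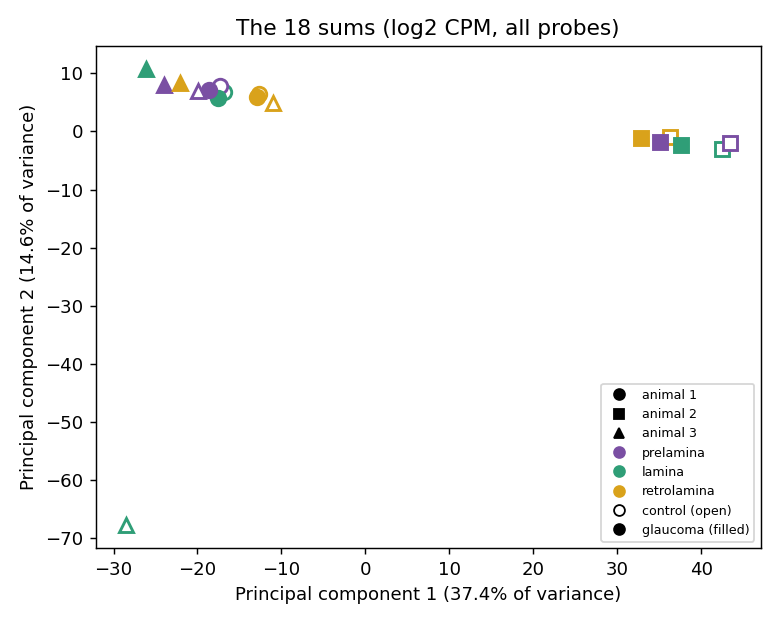
First and second principal components of log2 CPM for the 18 sums, with marker shape for the animal, colour for the region and filled markers for glaucoma eyes. Animal 2 lies apart on the first component (37.4% of the variance), and the control lamina of animal 3, with 200388 counts the shallowest sum, lies apart on the second (14.6%).

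Over the 18 sums, the animal accounted for 42.0% of the spread in log2 CPM, the region for 10.6% and the eye for 4.50%, against the 11.8%, 11.8% and 5.88% that their degrees of freedom alone would give. Among the 465 brighter probes the region accounted for 27.9% and the eye for 5.27%. The part of the eye difference that varied between animals accounted for 13.94% in these probes. Its degrees of freedom alone would give 11.8%. Over all probes this part was also larger than the eye share, but below 11.8%. The eye shares therefore do not show a difference shared by the animals.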

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

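The tests on animal 2 and the draws of matched libraries were chosen after the result was seen, and those of single libraries before their shares were computed but after the differences per animal of the named probes had been seen. A library far from the other 7 of its group was found in 9 of 37 checks of prelamina and lamina groups, where chance gives about 1 in 20. That rate does not apply to the 6 that concern named probes, which were chosen for their changes in these groups. Of 16 checks of library measures, 3 stood apart, with 0.8 expected by chance if the checks are independent. They are not, since 1 control lamina library of animal 2 stood apart in both aligned reads and saturation. In the control prelamina, RTS0028800 stood at 419 CPM in 1 library of animal 1 against 68.3 in the next (gap of 0.92 of the range). RTS0035701 stood at 488 against 85.3 CPM in that same library (0.932), so these are not separate events. RTS0035997 stood at 482 against 66.8 CPM in 1 library of animal 3 (0.904), and RTS0036735 at 63.4 against 39.0 CPM in animal 2 (0.601). In the control lamina, RTS0051294 stood at 1034 against 125 CPM in 1 library of animal 3 (0.907), and RTS0038859 at 317 against 82.7 CPM in 1 library of animal 1 (0.813). The latter is the L2 library that also held most of the excess of the probes called higher in L2 than in L1. Aligned reads were 85.6% in 1 glaucoma prelamina library of animal 1 (0.898) and 93.3% in 1 control lamina library of animal 2 (0.701). Saturation was 94.6% in the same control lamina library of animal 2 (0.924).

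The probes called higher in the prelamina than in the retrolamina differ from those called lower in how their excess is spread over libraries. For 69.4% of the 72 higher probes, 1 of the 8 prelamina libraries held over 50% of the summed excess, which fits an excess carried by single libraries, although 26.2% of probes with an unadjusted p of at least 0.5 gave as much. Among the 172 lower probes this was so for 0.581% over 36 retrolamina libraries. The largest share of 1 library had a median of 6.82% there, so most of these called probes did not rest on a single library. A share over 50% is harder to reach over 36 libraries than over 8. No value for probes with little sign of a difference was computed over 36, so the 69.4% and the 0.581% are not compared alike. In draws of 8 retrolamina libraries, a median of 0.581% of the 172 (0 to 11.05%) had over 50% in 1 library. The 172 had been called on sums of all 36, in which 1 library weighs less, and a draw leaves most libraries out. The draws therefore do not match how the 72 were chosen. With the retrolamina sums thinned to the depth of the prelamina sums, 100% of the 72 kept a positive difference, with a median log2 difference of 0.80 before and 0.84 after, and 36 still passed. The prelamina counts on which the probes had been chosen were not altered by this and the sign was expected either way, so depth and a regional difference, which the design names, both stay open for the 72.

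The 8 probes called between glaucoma and control eyes may rest in part on single libraries. For 25% of them, RTS0051294 and RTS0038859 in the lamina, 1 control library held over 50% of the excess, at 83.0% and 62.2%. For RTS0050382 in the lamina this share was 23.3% over 8 libraries, and for the 5 retrolamina probes it was 6.64 to 24.7% over 35 or 36 libraries. A share over 50% is harder to reach with more libraries, and no matched draws were made here. The retrolamina shares therefore do not show that single libraries played no part. Single libraries and an effect of glaucoma cannot be told apart for the set of 8 as a whole, and for these 6 probes an effect of glaucoma, which the design names, stays open.

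Animal 2 stands apart from animals 1 and 3, and it is the only animal of batch 2. Across 18815 probes, which are not independent replicates, its shift correlated at r = 0.679 with the batch shift of the reference materials, or 46.1% of its variance, which is consistent with a batch difference as a source of part of the separation. Subtracting the whole batch shift, whose own SD was 0.53, lowered the SD of the animal 2 shift only from 0.42 to 0.39, 2.10 times that between animals 3 and 1 (0.19). With the batch shift scaled by a fitted slope of 0.54, the SD left was 0.31, or 1.64 times. That remainder, from the animal or from a batch effect unlike that in the reference materials, cannot be told apart with 1 animal in batch 2.

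Other divisions of the same samples were tried, planned before their results were seen. With 3 animals there are 10 divisions of the 6 eyes or sums, too few for a share under 0.05. The glaucoma comparison gave 3 probes in the lamina, with 35 in the highest other division and 10 of 10 at least as large, and 0 in the prelamina (highest other 59, 10 of 10). With a real count of 0 the 10 of 10 is fixed in advance, here and for the prelamina labels below. In the retrolamina the glaucoma comparison gave 5, with a highest other of 181 and 7 of 10 at least as large. The 4 divisions that part the eyes of every animal gave at most 2 other probes in the prelamina, 7 in the lamina and 0 in the retrolamina, and the larger counts came from divisions that put both eyes of 2 animals together. With the animal as a block, these rest on the eyes of 1 animal. Their counts reflect the difference between the eyes of that animal, whose nature was not tested. For the 3 differences of effect, at 0 probes each, the highest others were 9, 8 and 20. Prelamina against retrolamina gave 244 with a highest other of 74 (1 of 10), lamina against retrolamina 143 with 22 (1 of 10), and lamina against prelamina 1 with 14 (7 of 10). The prelamina labels gave 0 with a highest other of 92 (10 of 10) and the lamina labels 4 with 64 (10 of 10). Across RL1 to RL5, 19 of 40 orders drawn gave at least the 13 probes of the real one (highest other 34), so chance is not excluded. For the batches, 1 of 40 draws, the real one, gave as many as 12869 (highest other 0), so chance is excluded.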

How the results depend on the processing

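Alternatives without shallow libraries (3 under 110000 counts, which takes away the whole control lamina of animal 3 and leaves 2 animals there), without outlying libraries, with brighter probes, with glaucoma eyes in place of control eyes for regions, and with an animal left out for the labels were chosen after seeing the data. For the 15 results of named probes that passed, 119 of 166 values under alternatives that alter the fit kept their direction and still passed, 46 no longer passed and 1 turned, RTS0051294 between lamina and retrolamina, at -0.27 in glaucoma eyes. RTS0027108 and RTS0038701 passed against the retrolamina under every alternative that held them. The no filter and all libraries kept alternatives removed nothing and the 50 probes per material alternative changed no set, so they say nothing about stability. Gene lists were not run, for lack of names, and probe sets were not run with voom or where filters left under 15 probes. The cause of the changes below was not tested, except that the outlying libraries were chosen for their values of named probes and the stricter filter left 73 probes in the glaucoma fit.

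In the order prelamina against retrolamina, lamina against retrolamina and lamina against prelamina, DESeq2 gave 118, 79 and 19 probes, the stricter filter 13, 8 and 7, and brighter probes 50, 48 and 4. The mean of log2 CPM gave 57 and 39 for the first 2 of these, and without outlying libraries they gave 138 and 83. Lamina against prelamina gave 42 in glaucoma eyes. Leaving out each animal gave 158 to 230, 96 to 151 and 6 to 53.

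For glaucoma in the lamina, upper-quartile factors gave 7 probes, the region alone 5, the stricter filter 1, brighter probes 0 in edgeR (36 at an unadjusted p under 0.05) and the fit without shallow libraries 6. In the retrolamina the stricter filter gave 1, the region alone 1, brighter probes 1, the fit without shallow libraries 3, and voom with a random eye block and the mean of log2 CPM with limma-trend 0 (159 and 110 at an unadjusted p under 0.05). The prelamina gave 2 without outlying libraries. Leaving out each animal gave 3 to 11 in the prelamina, 7 to 13 in the lamina and 0 to 11 in the retrolamina. The difference between lamina and retrolamina gave 0 to 9 probes with an animal left out and 1 without shallow libraries, that between prelamina and retrolamina 0 to 3, and that between lamina and prelamina 0 to 0.

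With no replicate block, the paired comparisons lost most calls, giving 0 probes for glaucoma in the lamina and 0 in the retrolamina, 20 for prelamina against retrolamina, 6 for lamina against retrolamina and 0 for lamina against prelamina. At an unadjusted p under 0.05 edgeR then gave 564, 70 and 382 for the 3 counts of 0. Dropping the block changed no other call count where it was run.

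For the labels, DESeq2 gave 0 for L2 against L1 and 2 across RL1 to RL5, and glaucoma eyes gave 1 for PL2 against PL1, 18 for L2 against L1 and 29 across RL1 to RL5, with 0 of them shared with control eyes. Without shallow libraries L2 against L1 gave 24, the fit without animal 3. Leaving out each animal gave 7 to 58, 3 to 24 and 37 to 54. Of the 5 probe sets, 1 passed for glaucoma in the lamina without shallow libraries (0 to 1 with an animal left out) and 1 for the difference between lamina and retrolamina without shallow libraries. It was BT474 each time, and with an estimated correlation camera's adjusted p was 0.33, 0.31 and 0.22. In the lamina, which had the shallowest sums, 13.4% of simulated 1.5-fold changes were recovered, and depth was not separated from spread there.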

Other observations

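Regions were also compared in glaucoma eyes, a comparison added after seeing the data, while the test in single animals was written down before its result was seen. Of the 172 probes lower in the prelamina than in the retrolamina of control eyes, 110 were called in the same direction in glaucoma eyes, where 1.499 would be shared by independent lists, and 171 had the same sign. The median log2 difference of all 172 was -0.85 in control and -0.66 in glaucoma eyes. Of the 72 called higher in the prelamina, 5 were called again (0.203 by independent lists) and 50 had the same sign. The median of all 72 was 0.80 in control and 0.08 in glaucoma eyes. Both lists were chosen on control eyes, so some shrinkage in other eyes follows from that choice. Against the lamina, 56 of 95 probes high in the retrolamina were called again (0.384 by independent lists) and 13 of 48 low there (0.138 by independent lists). The same sign was kept by 95 of the 95 and 32 of the 48. Both eyes come from the same animals, so these lists are not independent samples. RTS0027551 was 426 ± 165 CPM in the glaucoma lamina and 214 ± 72.2 CPM in the control lamina (SD, n = 3), a difference that did not pass in edgeR (adjusted p = 0.49) and was not seen in animal 3, at 292 and 287 CPM.

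RTS0027108 had 3221 ± 871 CPM in the glaucoma retrolamina against 4208 ± 266 CPM in the control retrolamina, and RTS0038701 had 338 ± 117 against 455 ± 45.1 CPM. Both were lower in 3 of 3 animals, and neither passed in edgeR (adjusted p = 1.00 for each). A hypothesis was that probes high in the retrolamina are at a lower level there in glaucoma eyes. For each animal such probes were chosen from the control eyes of the other animals. Their median glaucoma minus control log2 difference in the retrolamina was 0.053 in animal 1, -0.11 in animal 2 and -0.57 in animal 3, with 45.5%, 69.6% and 100% of the probes lower. A lower level shared by the 3 animals was therefore not shown. A median above 0 in any animal had been set beforehand as evidence against it, and animal 1 met that rule. Its value of 0.053 is near 0, with quartiles of -0.08 and 0.17 over probes that went both ways. These quartiles describe the spread of single probes, not the error of the median, and were considered only after the value was seen. The size of the fall in animal 3 may reflect that animal's disease, the placement of its regions of interest or its section, none of which was tested.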
